A study of Mus musculus with 3 samples.

How the data were processed

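RNA of 3 samples of mouse C2C12 cells (untreated, EGFP-transfected and DGK-zeta-transfected, 12 h) was labelled with biotin by the Affymetrix one-cycle protocol and hybridised to 1 array each, per the labels' protocols. The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version, the scaling target and detection calls are not given in the sources used here. From the values, every array has a mean of 500 between its 2nd and 98th percentile (499.9 each), so the deposited intensities had been scaled per array, and they were used with no further scaling. MAS5 combines the probes of a set near the 3' end of a transcript into 1 signal, so shortened labelled product can lower the signal of sets that lie further from that end; the positions of probes were not used here.

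The table has 22690 probe sets, 64 of them controls. Of the rest, 20380 have 1 gene symbol in the platform annotation, 691 have several and 1555 have none; the last groups were named nowhere. Symbols were looked up by gene ID in a RefSeq gene table of assembly GRCm38.p6, used for names only; 20364 probe sets were found and 0 symbols differed. No coordinates are given, since the sources used here name no genome build. A gene was represented by its brightest named probe set, the one with the highest mean log2 value over the 3 arrays, which gave 12393 genes, 4956 of them with 2 or more named probe sets. Values under the floor (the 50th percentile of all values pooled, 107) were set to the floor before log2, so a ratio with 1 array under the floor is a bound, written "at least", and such genes were not ranked.

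With 1 array per group no test across arrays can be run. Sizes alone were compared: a gene counted as higher or lower when its floored ratio was at least 2-fold, and as apart when this held against both other arrays. Chance overlap through the shared array came from 100 simulated sets. The measurement error within these arrays was taken from the 2 brightest probe sets of a gene, where both reached the floor on all 3 arrays; it covers different probes on 1 RNA extract, not the spread between cultures. The number of arrays limits the precision. For 33 gene lists of 1105 genes the median log2 ratio of members measured on at least 1 of both arrays was placed among 10000 random lists matched on size and on mean expression (20 bins), for lists with at least 4 such members; this describes these arrays and is no test. Bootstrap intervals used 2000 draws over genes.

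Named genes follow a rule: Dgkz, Btg2 and Ccnd1; the 10 highest and 10 lowest genes apart in DGK-zeta cells, ranked by the smaller of both ratios; the 10 highest and 10 lowest between EGFP and untreated; the 5 highest and 5 lowest in each comparison of DGK-zeta; up to 4 list members with the largest ratios and members at least 2-fold apart; and the 3' and 5' control probe sets. Exceptions are marked as named after their values were seen. Not every gene that meets the rule is printed.

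Alternatives were 3 other scalings (quantile normalization, equal medians over all named probe sets, equal medians over probe sets measured on all 3 arrays), floors at the 25th and 75th percentile, no floor, a pseudocount of 15.2 in place of the floor, the mean over a gene's probe sets, leaving out probe sets of suffix _x_at or _s_at, rules of 1.5-fold and 3-fold, random lists not matched on expression, list members measured on all 3 arrays, and second-brightest probe sets measured on all 3 arrays, and second probe sets chosen on both controls alone. The counting was tested on simulated data for the comparison of DGK-zeta with both controls over 12393 genes, with 200 altered ones: all 25 genes in each direction were counted at 3-fold, 4-fold and 8-fold, 9 of 25 higher and 10 of 25 lower ones at exactly 2-fold, and 22 of 12193 unaltered genes. The altered genes were drawn from those well above the floor on all 3 arrays. All probe sets of a gene were moved alike, with the spread between the controls as noise. The test thus does not cover genes near the floor, probe sets that disagree or a noisier array. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.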

Results

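The series measured RNA levels in C2C12 cells, a mouse myoblast line that can form muscle fibres in culture. It compared untreated cells with cells transfected with enhanced green fluorescent protein (EGFP), the control for transfection, and with cells transfected with diacylglycerol kinase zeta (DGK-zeta), an enzyme that converts diacylglycerol to phosphatidic acid. All 3 samples carry the time label 12 h, and cells had been plated for 18 h before transfection. Each of the 3 groups had 1 array of 22690 probe sets, so there are no replicates, no difference has a replicate check and no p-values are given. A gene was counted as measured on an array when its brightest probe set reached a signal of 107, the median of all values pooled. By that floor 6702 of 12393 genes were measured in untreated cells, 6843 in EGFP cells and 6625 in DGK-zeta cells, and 6434 on all 3 arrays. Median signals were 111 in untreated, 119 in EGFP and 92.5 in DGK-zeta cells. Over the 10512 probe sets measured on all 3 arrays, the correlation of log2 signals across probe sets, which are not independent replicates, was 0.981 between EGFP and untreated, 0.961 between DGK-zeta and EGFP and 0.947 between DGK-zeta and untreated.

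The first comparison concerns the transfected gene and the genes that the series title names, cyclin D1 and the antiproliferative gene Btg2. Dgkz, the transfected gene, ranked highest in both comparisons of the DGK-zeta array. Its brightest probe set had signals of 1500.1 in untreated, 1053 in EGFP and 13466 in DGK-zeta cells, which is 12.8-fold above EGFP and 8.98-fold above untreated. The other Dgkz probe set had signals of 188, 240.3 and 4315, a log2 ratio of 4.17 against EGFP and 4.52 against untreated. The sequence of the construct is not given in the sources used here, so whether these probe sets read its transcript or that of the cells is not known. Btg2, a member of the BTG/TOB antiproliferative family, lay close to the floor on every array. Its brighter probe set had signals of 94.7 in untreated, 116 in EGFP and 117 in DGK-zeta cells, a log2 ratio of 0.01 against EGFP, and the other stayed under the floor at 72.1, 85.1 and 39.1. Ccnd1, which encodes cyclin D1, an activator of the kinases that drive cells through G1, gave different ratios from its 3 probe sets. The brightest had signals of 3889 in untreated, 3735 in EGFP and 4758 in DGK-zeta cells, a log2 ratio of 0.35 against EGFP and 0.29 against untreated. The next had 4154, 3484 and 4026, a log2 ratio of 0.21 against EGFP and -0.05 against untreated. The last had 1731, 1574 and 323, a log2 ratio of -2.28 against EGFP and -2.42 against untreated. With the mean over its probe sets, the Ccnd1 log2 ratio was -0.58 against EGFP and -0.73 against untreated, opposite in direction to its brightest probe set.

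**Figure D1:**
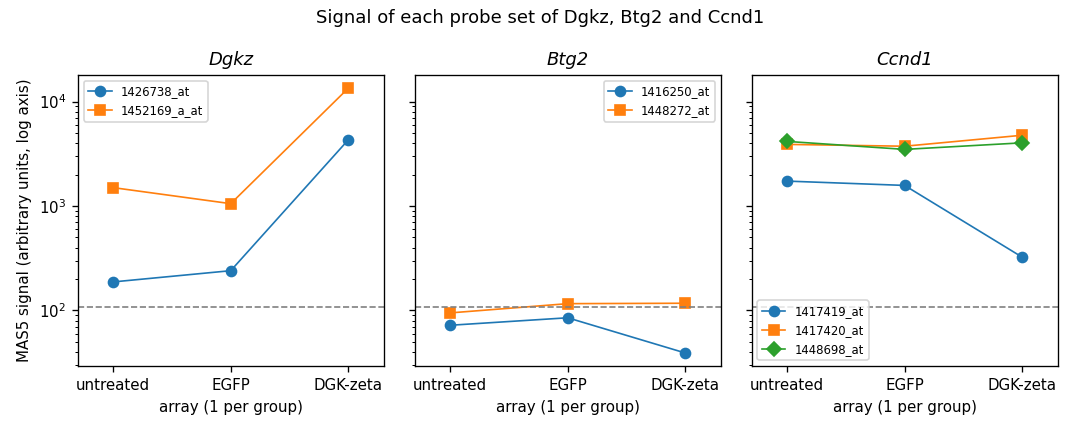
MAS5 signal (arbitrary units, log axis) of each probe set of Dgkz, Btg2 and Ccnd1 on the untreated, EGFP and DGK-zeta arrays, 1 array per group, with the floor of 107 as a dashed line. Both Dgkz probe sets are highest on the DGK-zeta array, both Btg2 probe sets lie near or under the floor, and 1 of the 3 Ccnd1 probe sets drops to 323 on the DGK-zeta array while the others stay between 3484 and 4758.

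The comparison of DGK-zeta with EGFP asks which transcripts differ with the kinase when both cultures were transfected. Dgkz and Rpgrip1 had the highest ratios among genes measured on both arrays, and Rpgrip1, a gene known from photoreceptors, was 3.19-fold higher. The other Rpgrip1 probe sets had signals between 1.8 and 12.3 on every array, under the floor. Behind both genes came Tspan12, a tetraspanin membrane protein, at 2.66-fold, Snrnp40, a spliceosome component, at 2.60-fold, and Prss23, a secreted serine protease, at 2.32-fold higher. The other probe set gave a log2 ratio of 0.10 for Snrnp40 and 0.18 for Prss23. Among the lowest genes, Gna13, the alpha subunit of a heterotrimeric G protein, was 6.86-fold lower and Kif5b, a kinesin heavy chain, was 5.47-fold lower. Other probe sets measured on all 3 arrays gave log2 ratios of -0.43, 0.36 and 0.72 for Kif5b. Those of Gna13 gave -0.72, -0.23 and 0.20. Rasal2, a GTPase-activating protein for Ras, was 4.84-fold lower, Brd2, a bromodomain protein that binds acetylated histones, 4.54-fold lower, and Cnot6l, a deadenylase of the CCR4-NOT complex, 4.37-fold lower. In all, 24 genes were at least 2-fold higher and 197 at least 2-fold lower in DGK-zeta cells. This split rested on the scaling of the arrays: it was 52 higher and 108 lower after quantile normalization, 42 and 143 with equal medians over probe sets measured on all 3 arrays, and 164 and 51 with equal medians over all named probe sets. A single probe set carried an SD of 0.40 on the log2 scale in this comparison, from the difference between the 2 brightest probe sets of 2251 genes.

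Genes of the actin cytoskeleton had the lowest percentile of all lists against EGFP. The lowest median, -0.25, was that of myogenic regulators, inside the random range at percentile 8.95, with Snai1, a transcriptional repressor, at -1.12 and Myf5 at 0.73. Of 30 measured members of the actin list 6 had ratios above 0, and its median of -0.21 lay at percentile 0.01 of matched random lists. Equal medians over all named probe sets, which move all genes of an array alike, put the median at 0.15. Itga5, the fibronectin receptor subunit, was the member at least 2-fold lower (log2 ratio -2.06), followed by Tln1, which links integrins to actin, at -0.96, Cnn2, a calponin, at -0.76 and Zyx, a focal adhesion protein, at -0.75. Extracellular matrix genes had a median of -0.14 at percentile 1.72, or 0.22 with equal medians over all named probe sets, with 8 of 37 members above 0. Of these genes 4 were at least 2-fold lower: Col8a1 at -1.99, the membrane-type matrix metalloproteinase Mmp14 at -1.76, Sparc at -1.16 and Lama5 at -1.03. The second-brightest probe set of Sparc gave 0.01 in place of -1.16, and that of Lama5 -0.29 in place of -1.03. The matrix list was inside the central 95% without probe sets of suffix _x_at or _s_at (percentile 4.88), by second-brightest probe sets (5.05) and among random lists not matched on expression (8.15). Actb, the cytoplasmic actin gene often used as a reference, was 3.22-fold lower than in EGFP cells by its brightest probe set. Its other, much dimmer one (191 in EGFP and 325 in DGK-zeta cells) gave a log2 ratio of 0.76. The ratio of the Actb 3' to its 5' control probe set was 2.55 in DGK-zeta, 1.43 in EGFP and 1.27 in untreated cells. For Gapdh the same ratio was 0.931, 0.902 and 0.841, and the 5' probe set of the transferrin receptor was under the floor on all 3 arrays.

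Other groups lay inside the range of random lists in the comparison with EGFP. Cell cycle lists were among them: G1 cyclins and kinases had a median of 0.23 (percentile 95.2) with no member 2-fold apart, although Ccnd2 was at -0.98 and Ccnd3 at -0.64, and E2f1, a transcription factor of S phase entry, was at -0.96 by its brightest probe set and -0.02 by the other, within an RB and E2F list of median 0.02. CDK inhibitors had a median of -0.21 over 4 members, with Cdkn1a, which encodes p21, at 0.10 and Cdkn1b at -0.29. The 48 DNA replication genes had a median of 0.03 and the 55 measured mitosis genes of 0.02, with no member 2-fold apart. In the BTG/TOB family Tob1 was at 0.61, Tob2 at 0.17 and Btg1 at 0.00. Among genes of diacylglycerol and protein kinase C signalling (median -0.10), Pip5k1a, a phosphatidylinositol phosphate kinase, was at -1.71, but its second-brightest probe set by the controls was at 0.06. TGF-beta and SMAD targets had a median of -0.13 (percentile 7.63), with Inhba at -1.54, Tgfb1 at -1.31 and Tgfb1i1 at -1.19. Cholesterol synthesis genes had a median of -0.17 (percentile 3.80), with Srebf2, the transcription factor that controls them, at -1.02. Only 2 of the 28 lists with a percentile were outside the central 95%, where 1.40 would be by chance.

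The comparison of DGK-zeta with untreated cells joins the effect of the kinase with that of transfection. Snrnp40 was 4.60-fold higher, Tspan12 4.43-fold, Dctn6, a dynactin subunit, 3.61-fold and Snrpd3, an Sm core protein of the spliceosome, 3.39-fold higher than in untreated cells. The other probe set gave a log2 ratio of -0.06 for Snrnp40 and 0.39 for Dctn6. Gna13 was 9.30-fold lower, Brd2 8.59-fold, Kif5b 7.96-fold, the mitochondrial carrier gene Slc25a30 7.30-fold and Ago2, the Argonaute protein of RNA silencing, 5.96-fold lower. Other probe sets measured on all 3 arrays gave log2 ratios of -1.41, 0.96 and 1.29 for Kif5b. Those of Gna13 gave -1.14, -0.37 and 0.36. In total 92 genes were at least 2-fold higher and 192 lower. With quantile normalization the split was 131 and 136, with equal medians over measured probe sets 125 and 146, and with equal medians over all named probe sets 253 and 96. The SD of a single probe set was 0.50 on the log2 scale.

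Matrix and actin genes were low and interferon-stimulated genes high against untreated cells, by the same DGK-zeta array as in the comparison with EGFP, so that low lists found in both comparisons are not independent. Extracellular matrix genes had a median of -0.29 (percentile 0.00), or -0.03 with equal medians over all named probe sets, with Mmp14 at -2.50, Col8a1 at -1.65, Fbln2 at -1.14 and Col1a2 at -1.05, and actin cytoskeleton genes a median of -0.26 (percentile 0.00), or 0.0065 with equal medians over all named probe sets, with Itga5 at -1.21. The second-brightest probe sets put both lists inside the random range, at percentile 45.7 for matrix and 15.6 for actin genes, over the 20 of 37 and 15 of 30 genes that have them, and turned Col1a2 to 0.20. Interferon-stimulated genes, which answer foreign nucleic acid and interferon, had a median of 0.32 (percentile 100) over 29 measured members, 21 of them above 0. Ifit1 was at least 2.93-fold and Ccl5 at least 2.28-fold higher, both being under the floor in untreated cells, and Ifi204 was 2.21-fold higher. The 4 interferon-stimulated genes with a second-brightest probe set lay at percentile 73.4 by it. Hypoxia and glycolysis genes had a median of 0.22 (percentile 99.7), with the glucose transporter Slc2a1 at 0.93, Ndrg1 at 0.84 and Vegfa at 0.74, but other measured probe sets gave 0.11 for Slc2a1, -0.90 for Ndrg1 and -0.79 for Vegfa at the lowest. That list was inside the random range with the mean over each gene's probe sets (percentile 79.6), by second-brightest probe sets (80.7) and without probe sets of suffix _x_at or _s_at (82.1).

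Among cell cycle lists, mitosis genes were slightly lower than in untreated cells. Their list had a median of -0.12 (percentile 0.24), or 0.14 with equal medians over all named probe sets, with Kif11, a spindle motor, at -0.74, Nuf2 at -0.71 and Ube2c at -0.70, while Cenpe was at least 2.40-fold lower and under the floor in DGK-zeta cells. Among random lists not matched on expression the mitosis list lay at percentile 4.85, inside the central 95%. The DNA replication list had a median of -0.09 (percentile 2.48), or 0.17 with equal medians over all named probe sets and 0.0006 with those over measured probe sets, with Cdc45 at -0.70, Pola2 at -0.63 and Tk1 at -0.62. Of 6 other settings only quantile normalization kept that list outside the central 95% (percentile 1.76). Among random lists not matched on expression it was inside, at percentile 11.8. Ccnd2 was 2.21-fold lower and Tob1 2.27-fold higher than in untreated cells, in lists whose medians of 0.08 and 0.14 were inside the random range. Among myogenic regulators, of median -0.24 (percentile 3.72), Six4 was at -1.39 and Igf1r at -1.07, and Myf5, a myogenic transcription factor, at 0.94. Immediate early genes had a median of -0.01, with Hbegf at -1.57 and Junb at least 3.04-fold lower, but the second-brightest probe set of Hbegf was at 0.03. In this comparison 6 of 28 lists were outside the central 95%.

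Genes that stood apart in DGK-zeta cells from both controls were mostly lower ones. Besides Gna13, Kif5b, Rasal2, Brd2 and Cnot6l, the lowest were Sp1, a general transcription factor (2287 in untreated, 1579 in EGFP and 388 in DGK-zeta cells), Bicd2, a dynein adaptor (1536, 1062 and 263), Slc25a30 (1154, 638 and 158), Glg1, a Golgi glycoprotein (1336, 1186 and 306) and Mmp14 (1484, 891 and 262). Besides Dgkz, Tspan12, Snrnp40 and Prss23, the highest were Tank, an adaptor of NF-kB signalling (376, 368 and 833), Ccdc47, a protein of the endoplasmic reticulum (1152, 1081 and 2504), the pseudogene Tes3-ps (130, 170.1 and 366), Vps37c, an ESCRT component (214, 208 and 458), Mtfr1, a regulator of mitochondrial fission (380, 392 and 832), and Dctn6 (442, 763 and 1595). The counts were 19 genes higher than on both controls and 99 lower, of which 12 and 88 were measured on all 3 arrays. The same count was 9 higher and 1 lower for the EGFP array, and 16 higher and 7 lower for the untreated array. Both comparisons share the DGK-zeta array, so chance overlap was simulated: 100 sets of 3 arrays without effects, with the spread between the EGFP and untreated arrays, gave on average 16.1 genes higher and 7.95 lower, with maxima of 26 and 19. Independent lists of these sizes would share 0.325 higher and 5.56 lower genes. As scaled by the depositors, the count of higher genes was thus inside the simulated range and the count of lower genes above it. The split was 36 higher and 64 lower after quantile normalization, 30 and 74 with equal medians over measured probe sets, and 92 and 32 with equal medians over all named probe sets. With each of these scalings both counts lay above the simulated maxima. The simulated arrays held no scaling difference and were not made anew for them, so the reading of the higher genes rests on the scaling. The simulated arrays also held only the spread between the controls. The SD of a single probe set was 0.27 there, but 0.40 and 0.50 in the comparisons of DGK-zeta with EGFP and untreated. A noisier DGK-zeta array was not simulated.

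**Figure D2:**
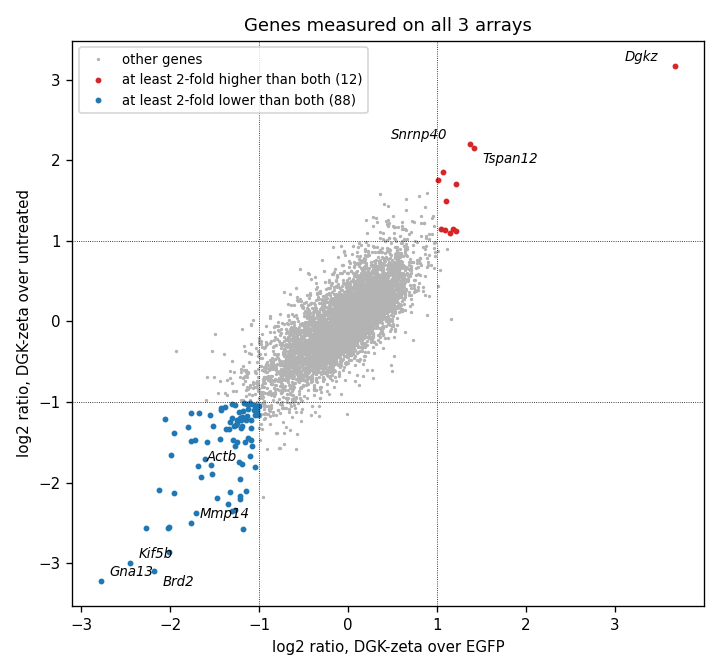
Log2 ratio of DGK-zeta over EGFP (horizontal) and of DGK-zeta over untreated (vertical) for the 6434 genes measured on all 3 arrays, with dotted lines at 2-fold and 1 point per gene. Red points are the 12 genes at least 2-fold higher and blue points the 88 at least 2-fold lower than both controls as scaled by the depositors, a split that turns to more higher than lower genes (92 and 32, genes under the floor included) with equal medians over all named probe sets; both axes share the DGK-zeta array, so points align along the diagonal in part by construction.

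Second probe sets of the same genes repeated some of these differences and not others. Dgkz was the 1 gene higher than both controls by at least 2-fold with each of its 2 brightest probe sets. Second probe sets were chosen on the controls alone, as the brightest other one at or above the floor in untreated and EGFP cells. Among lower genes, 11 of 42 with such a probe set were at least 2-fold lower than both controls by it too. They are Gna13, Bicd2, Slc25a30, Glg1, Mmp14, and, named after their values were seen, Ywhae, a 14-3-3 protein, Fzd2, a Wnt receptor, Lpcat1, an acyltransferase of phospholipids, Pdap1, Dclk1 and Hipk2. The second probe set of Gna13, under the floor in DGK-zeta cells, was at least 5.13-fold below EGFP, and that of Mmp14 at least 2.94-fold. Further probe sets, measured on all 3 arrays, repeated less of this. Their log2 ratios against EGFP were -0.72, -0.23 and 0.20 for Gna13, -0.04 for Glg1, and 0.36 and 0.72 for Kif5b. In 27 of the 42 genes the second probe set was lower than both controls, with a median of -0.50 for the mean of both log2 ratios where the brightest had -1.44, and in 4 of 8 higher genes it was higher. Kif5b was at -0.43 against EGFP by the second probe set and Brd2 at -0.57, in place of -2.45 and -2.18. Cnot6l was at 0.01 and Vps37c at -1.23, in place of -2.13 and 1.14. Ccdc47 was at -0.06, Mtfr1 at -0.09 and Snrnp40 at 0.10, in place of 1.21, 1.09 and 1.38. Prss23 was at 0.18 and Dctn6 at 0.53, in place of 1.22 and 1.06. Over all 2251 genes with 2 probe sets measured on all 3 arrays, the median of second minus brightest was -0.13 (95% bootstrap interval over genes -0.16 to -0.11) in the ratio of DGK-zeta to EGFP and 0.0024 (-0.01 to 0.02) in that of EGFP to untreated. The former was -0.09 with probe sets ranked by the 2 controls and -0.19 with probe sets ranked by the DGK-zeta array. Of 4 poly-A control transcripts only dap was above the floor throughout, with a 3'/5' ratio of 7.70 in DGK-zeta, 6.94 in EGFP and 3.58 in untreated cells. With low signals included, all 4 had their highest 3'/5' ratio in DGK-zeta cells.

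**Figure D3:**
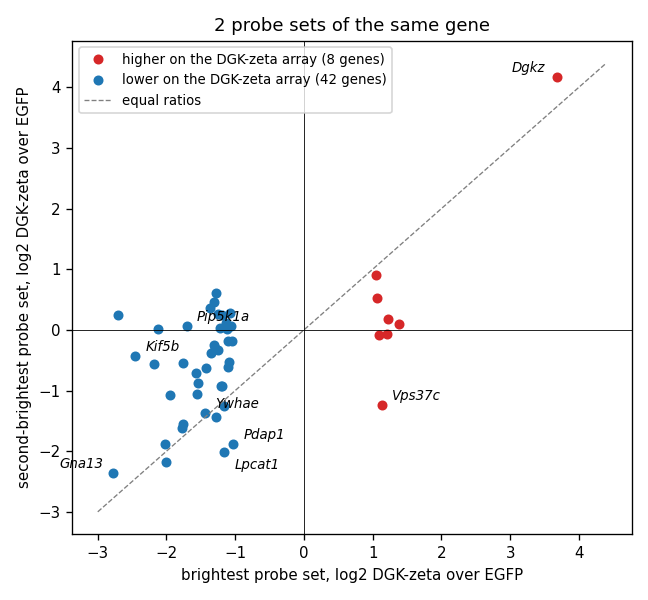
Log2 ratio of DGK-zeta over EGFP by the brightest (horizontal) and second-brightest probe set (vertical, chosen on the controls, values under the floor set to it) for the 8 higher (red) and 42 lower (blue) genes that have both, with the dashed line marking equal ratios. Dgkz reaches 3.68 and 4.17, while most lower genes lie above the line, such as Kif5b at -2.45 and -0.43.

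The comparison of the controls sets EGFP against untreated cells, with 1 array each, so transfection is not separated from culture or array. Anpep, a membrane aminopeptidase, was 2.97-fold higher in EGFP cells, Tsc22d4 2.52-fold, Nenf, a secreted neurotrophic factor, 2.35-fold and Ifitm1, an interferon-induced membrane protein, 2.28-fold higher. Cd99, Cdk5r1, Dnm1, Dtx3, Strada and Tle5 followed, between 2.08-fold and 2.22-fold higher. Gatad2b, a subunit of a nucleosome remodelling complex, was 4.81-fold lower, Ankhd1 2.99-fold, Ago2 2.63-fold and Bbx 2.43-fold lower. Other low genes were Sntb2, 1810058I24Rik, Akap2, Rps27 and Acsbg1, between 2.16-fold and 2.31-fold lower. In all 25 genes were at least 2-fold higher and 21 lower, with 21 and 27 after quantile normalization and 9 and 31 with equal medians over all named probe sets. The SD of a single probe set was 0.27 on the log2 scale.

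Interferon-stimulated genes were higher in EGFP than in untreated cells. Their median was 0.34 (percentile 100), and 25 of 28 measured members were above 0, among them Ifit1, at least 2.88-fold, Ccl5, at least 2.66-fold, and Tapbp, a peptide loading protein, 2.08-fold higher, with Isg20 at 0.91. Between DGK-zeta and EGFP cells the same list had a median of -0.0043 (percentile 85.7). Cholesterol synthesis genes had a median of 0.22 (percentile 99.8), with Mvd at 0.83, Dhcr7 at 0.74 and Cyp51 at 0.59. NRF2 targets had a median of 0.18 (percentile 99.99), with Srxn1 at 0.53, Hmox1 at 0.51 and Cat at 0.49, but -0.0026 by second-brightest probe sets. Hypoxia and glycolysis genes had a median of 0.14 (percentile 99.7), with Aldoa at 0.49. That list was inside the random range with the mean over probe sets (percentile 95.2) and among random lists not matched on expression (96.0). Diacylglycerol and protein kinase C signalling genes had a median of 0.23 (percentile 99.5), with Plcb3 at 0.58 and Prkd3 at 0.41, and lay inside the random range with the mean over probe sets (percentile 92.2), without probe sets of suffix _x_at or _s_at (95.6) and by second-brightest probe sets (61.7). Heat shock genes had a median of 0.08 (percentile 99.2), or -0.02 with equal medians over all named probe sets and -0.01 by second-brightest probe sets. The mean over probe sets put them at percentile 93.9, and random lists not matched on expression at 83.5. Mitosis genes had a median of -0.11 (percentile 0.21), with Kif11 at -0.61 and Cenpe at least 2.40-fold lower, and DNA replication genes a median of -0.09 (percentile 1.69), with Rfc3 at -0.81 and Fen1 at -0.55. The other probe set was at -0.08 for Rfc3 and at 0.0009 for Fen1. DNA replication genes were inside the random range without probe sets of suffix _x_at or _s_at (percentile 3.77) and by second-brightest probe sets (23.2). The lists outside the central 95% numbered 8 of 28 here, and since this comparison and that of DGK-zeta with untreated cells share the untreated array, lists found in both are not independent.

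**Figure D4:**
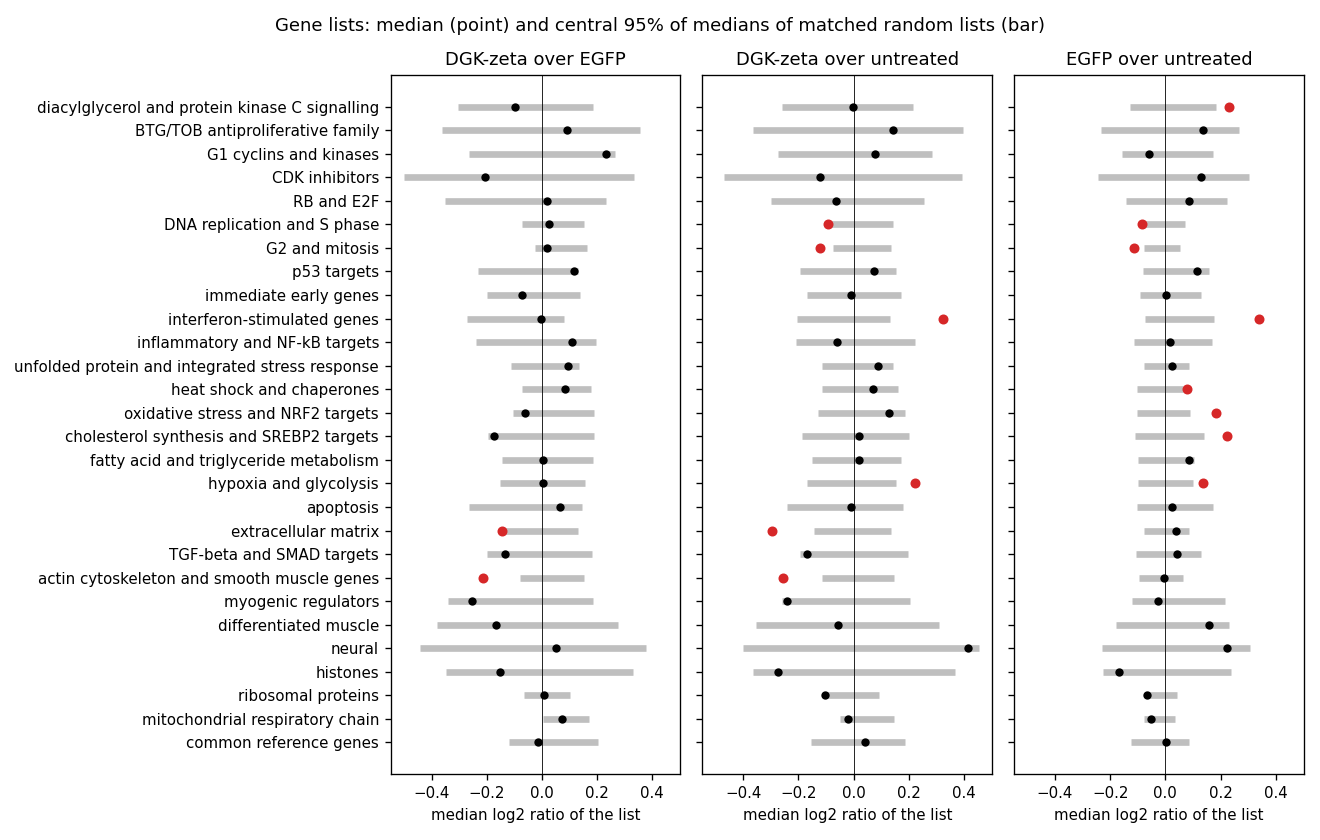
Median log2 ratio of each of 28 gene lists (points) in the 3 comparisons, with grey bars for the central 95% of medians of 10000 random lists matched on size and mean expression. Red points lie outside the bars: 2 lists for DGK-zeta over EGFP, 6 for DGK-zeta over untreated and 8 for EGFP over untreated, as scaled by the depositors; equal medians over all named probe sets move all genes alike and so turn the sign of 6 of these medians, of which all but that of DNA replication stay outside random lists on the same side (for DGK-zeta over EGFP extracellular matrix and actin, for DGK-zeta over untreated DNA replication, mitosis and actin, for EGFP over untreated heat shock).

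Markers of other cell types were sparsely measured, and only the neural and differentiated muscle lists had enough members to be placed among random lists, inside whose range both lay. Endothelial markers had 0 of 13 measured. Against EGFP, haematopoietic markers had 2 of 23 measured, with Cd14 at -0.14, epithelial markers 2 of 17 and adipocyte markers 2 of 11, with Lpl at 0.22; Cd14 and Lpl were named after their values were seen. Neural markers had 5 measured, with Nefl at 0.25 and Nefm at 0.22 (median 0.05). Of 50 differentiated muscle genes on the array 9 were measured, with Des, the muscle intermediate filament, at -0.96 against EGFP and -0.73 against untreated, and a list median of -0.17 at percentile 20.3 against EGFP. The 14 reference genes had a median of -0.01 against EGFP, with Polr2a at -0.57, Hprt at 0.28 and Actb as given above.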

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

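No test in this part was chosen after its result was seen. Among the 2246 probe sets with no gene or several genes in the annotation, which enter no comparison of named genes, 1 was at least 2-fold higher in DGK-zeta cells than in both controls. It had signals of 45.5 in untreated, 95.7 in EGFP and 236 in DGK-zeta cells, both control values being under the floor. It drew attention because it is a signal above both controls in data that the comparisons did not use. On the other side, 30 such probe sets were at least 2-fold lower than both controls.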

How the results depend on the processing

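The settings were listed before the data were examined, except equal medians over probe sets measured on all 3 arrays, the second-brightest probe set (with the brightest over the same genes) and the calls by both of 2 probe sets, which were chosen after the results were seen. No paired analysis was possible because each group had 1 array. Of the alternative values of gene counts that answer a comparison, 25 stayed within 1.5 times the reported count and 67 did not. Of the other named genes' ratios 3385 moved by less than the SD of a probe set, 360 by more, and 18 of at least 2-fold turned sign. This tally pools settings that could hardly move a ratio. Over all named genes, all 395 ratios stayed under each equal-median scaling. All 141 stayed by the brightest probe set over the same genes, which is largely the same probe set. By second-brightest probe sets 58 stayed, 69 moved by more and 14 turned sign. Of the list medians 710 moved by less than the SD of random lists, 244 by more, and 9 from lists outside the central 95% turned sign. Of 112 named ratios of at least 2-fold, 105 remained so after quantile normalization, 90 with equal medians over all named probe sets, 38 with the floor at the 75th percentile, 81 with the mean over probe sets, and 9 of 41 by second-brightest probe sets. Low signals set the limits: 6434 of 12393 genes reached the floor on all 3 arrays.

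Counts follow as higher and lower genes, for DGK-zeta against EGFP, DGK-zeta against untreated, EGFP against untreated, and DGK-zeta against both controls. With the floor at the 25th percentile they were 194 and 613, 351 and 520, 380 and 251, and 98 and 245. With the floor at the 75th percentile they were 7 and 24, 31 and 52, 3 and 5, and 7 and 18. Without a floor they were 1051 and 1612, 1247 and 1482, 1339 and 1154, and 463 and 861. With a pseudocount in its place they were 208 and 498, 317 and 488, 328 and 263, and 70 and 202. These follow from how much of the low signals each setting lets in. A rule of 1.5-fold gave 243 and 806, 487 and 682, 286 and 105, and 152 and 449, and a rule of 3-fold gave 3 and 30, 11 and 44, 0 and 4, and 3 and 19, by construction more and fewer.

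Scaling moved the split itself. Equal medians over all named probe sets gave 164 and 51 against EGFP, 253 and 96 against untreated, 9 higher for EGFP against untreated, and 92 and 32 against both controls, and put the median log2 ratio of genes measured on all 3 arrays at 0.35, 0.25 and -0.09 in the 3 comparisons, where it had been -0.01, -0.01 and 0.01. Quantile normalization gave 52 and 108 against EGFP and 36 and 64 against both controls. Equal medians over measured probe sets gave 42 higher against EGFP and 30 higher against both controls. The mean over probe sets gave 15 higher against EGFP and 11 higher against both controls, and a call by both of 2 probe sets measured on all 3 arrays left 1 higher and 5 lower, over fewer genes. That choice drops probe sets that are under the floor in DGK-zeta cells. With the second probe set chosen on both controls alone, 1 higher and 11 lower were left.

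Under equal medians over all named probe sets the list medians that turned sign were 0.22 for extracellular matrix and 0.15 for actin against EGFP, 0.17 for DNA replication, 0.14 for mitosis and 0.0065 for actin in DGK-zeta against untreated, and -0.022 for heat shock in EGFP against untreated. This scaling moves all genes of an array alike, by the shift given above. Equal medians over measured probe sets gave 0.0006 for DNA replication against untreated. Second-brightest probe sets gave -0.012 for heat shock and -0.0026 for NRF2 targets in EGFP against untreated.

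Single genes turned or moved with the probe set taken, and except for Ccnd1, treated below, the cause was not tested gene by gene. With the mean over probe sets Ccnd1 was at -0.58 against EGFP and -0.73 against untreated, Dgkz at 3.85 against untreated, Pip5k1a at 0.064 and Vps37c at -0.046 against EGFP. Ccdc47 was at -0.062 against EGFP and -0.10 against untreated, both without probe sets of suffix _x_at or _s_at and by its second-brightest probe set. By second-brightest probe sets measured on all 3 arrays, against EGFP and untreated in turn, Dgkz was at 4.17 and 4.52, Cnot6l at 0.0085 and 0.48, Mtfr1 at -0.089 and -0.0051, Pip5k1a at 0.61 and 0.88, and Vps37c at -1.23 and -0.48. Sparc was at 0.014 against EGFP by that probe set, and against untreated Col1a2 was at 0.20, Hbegf at 0.032 and Snrnp40 at -0.059.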

Other observations

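Tests chosen only after the result was seen are those of a shorter labelled product for the lower genes, of low signal for Ccnd1 and of plasmid transfection for the interferon-stimulated genes. Among p53 targets Trp53inp1 was 2.05-fold higher in DGK-zeta than in EGFP cells and Mdm2, which feeds back on p53, had a log2 ratio of 0.70 (0.11 by its other probe set), while Phlda3 was at -0.89, with a list median of 0.12 at percentile 96.4. Against untreated cells Gadd45a was 2.24-fold higher and Ccng1 at 0.85. Atf5, a transcription factor of the integrated stress response, was 2.18-fold lower than in EGFP cells, in a list of median 0.10 (percentile 89.9). Trib3, in the same list, was at least 2.85-fold higher than in EGFP cells, but at a log2 ratio of 0.04 by its other probe set. Cat, the peroxide-degrading catalase, was at 0.82 against EGFP and 1.31 against untreated, while Gsr was at -0.58 against EGFP. Fads2, a fatty acid desaturase, was 2.94-fold lower than in EGFP cells, and Bak1, which opens the outer mitochondrial membrane in apoptosis, 3.01-fold lower. Nfkb2 was 2.22-fold lower than in EGFP cells within a list of median 0.11. Ribosomal protein genes had a median of 0.0089 against EGFP over 42 members, with Rps27 at 1.15 and Rps6 at 0.87, and -0.10 against untreated (percentile 2.64). Rps27 was at 0.03 and Rps6 at 0.90 against untreated, and the Rps27 signal was lowest in EGFP cells. Respiratory chain genes had a median of 0.07 against EGFP, with Sdhc at -0.81 (-0.06 by its other probe set). The 4 measured histone genes had a median of -0.15 against EGFP, with Macroh2a1 at -0.85. Of the 10 diacylglycerol kinase genes, 4 were on the array, and Dgka, named after its value was seen, was the other one measured, at -0.02 against EGFP.

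More genes were lower than higher on the DGK-zeta array than on both controls. The 99 lower genes exceed the highest of 100 simulated sets without effects, 19, which argues against a spread like that between the controls as the whole cause. The simulation cannot speak to a noisier DGK-zeta array, since it held only the spread between the controls. The SD of a single probe set was 0.40 for DGK-zeta against EGFP and 0.50 against untreated, but 0.27 for EGFP against untreated. Scaling cannot be told apart from a difference in the cells: after quantile normalization the lower genes were 1.78 times the higher ones, between the bound of 1.5 set for scaling as the cause and that of 2 set against it. A shorter labelled product cannot be told apart either. Second-brightest probe sets of the lower genes, chosen on the controls, had 0.345 of the mean log2 ratio of the brightest (95% interval 0.133 to 0.561). The bounds, set after the result was seen, were an interval under 0.5 for it and one at 0.8 or more against it. The ratio lay on the side set for it, under 0.5, but the upper end of the interval passed 0.5. Noise in single probe sets would also give a low value. Only 1 of the 4 poly-A controls, which are added to the RNA, was above the floor throughout, too few to decide. With low signals included, all 4 had a higher 3'/5' log2 ratio in DGK-zeta cells, on average by 0.37 against EGFP and 0.74 against untreated. That is the direction of a shorter product, but it rests largely on signals under the floor. The mean of EGFP against untreated was 0.38 too. For the 4 hybridization controls the means of DGK-zeta were -0.03 against EGFP and -0.11 against untreated. An effect of DGK-zeta itself was not tested.

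The 3 Ccnd1 probe sets disagree, with a gap of 2.63 on the log2 scale between the highest and the lowest ratio of DGK-zeta to EGFP. Low signal is argued against, since the lower probe set still had 3.02 times the floor in DGK-zeta cells. Gaps as large were found in 7 of 709 genes with 3 or more measured probe sets, 0.987% (exact binomial 95% interval 0.398 to 2.02), against 1 gene for EGFP over untreated. A share over 5% had been set for a shorter labelled product as the cause and one under 1% against it. The share was under 1%, the result set against it, and the whole interval lay under 5%. The bounds were set on the share alone, without its interval. That interval reaches above 1%, and such gaps were more frequent than for EGFP over untreated, so a shorter product is not excluded. For a different use of transcript ends no probe positions were used and no test was run.

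Interferon-stimulated genes were higher on both transfected arrays. After quantile normalization the median ratio of EGFP to untreated was 0.308, above the range of random lists (-0.10 to 0.14), the result set against scaling. This does not decide on scaling, because the random lists come from the same rescaled arrays and move with the list. It shows that the list stood above other genes of like expression under that scaling too. Transfection with plasmid DNA, whichever insert it carries, cannot be told apart from a single low untreated culture. Between DGK-zeta and EGFP the list lay at percentile 85.7, inside the range of random lists, but both comparisons with untreated cells share 1 untreated array and the test largely restates the pattern, and cells given the reagent alone were not analysed here.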
